A study of Apis mellifera with 12 samples.

How the data were processed

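Circular RNAs (circRNAs) are closed loops that form when a downstream splice donor joins an upstream splice acceptor, a reaction called back-splicing. They were measured in the ovaries of honey bee (Apis mellifera) queens, in 12 libraries from 4 groups of 3 samples each: virgin queens, normally laying queens, queens whose laying was inhibited by a cage for 7 days inside their own colony, and queens that had been caged for 7 days, released, and sampled on day 8, when they were laying again. Per the labels' protocols, 5 µg of RNA per sample was depleted of ribosomal RNA, digested with RNase R (an exonuclease that degrades linear RNA), made into directional libraries and sequenced as paired-end reads of 150 bp on an Illumina HiSeq instrument, and the reference genome was Amel_4.5. Bowtie is named in the submitters' processing notes, without a version. The circRNA caller and its thresholds are not given in the sources used here.

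The authors deposited one table of circRNAs with a position, a strand and a read count per library, and the counts are whole numbers whose totals differ between libraries. A second set of deposited columns, headed TPM per the file headers, holds each count divided by its library's total of circRNA reads and scaled to one common total. Recomputing this ratio gave the deposited values to within 4.989e-06, so these deposited columns hold CPM, with no length term, and are called CPM throughout. No library held a count of 1, and the smallest count above 0 was 2. A circRNA listed at 0 therefore had fewer than 2 reads or was not listed for another reason, so no limit was computed from a count of 0 and no fold is given against a group in which all libraries were listed at 0. Positions are given as the table gives them, in Amel_4.5; whether its starts count from 0 or from 1 is not given in the sources used here. The total of circRNA reads was between 66487 and 206697 per library, and the precision of a value is limited by these totals and by the spread between replicates.

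Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, TMM scaling). All 4 groups entered one fit, which pooled the spread over 12 libraries. CircRNAs with low counts were removed by filterByExpr with a minimum count of 5 and a minimum total of 15, which left 3215 of 20244. Printed fold changes come from this fit with TMM scaling, while printed CPM are scaled by library totals, so a fold differs from the ratio of the CPM means beside it. A circRNA was called when its Benjamini-Hochberg adjusted p was under 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic, and 95% intervals used the t distribution with the degrees of freedom of the fit. The 3 main comparisons were laying vs virgin, caged vs laying and released vs caged, and released vs laying and caged vs virgin were secondary. Differences between groups in a single value per library used an exact two-sided permutation test, whose smallest p is 0.1 with 3 libraries against 3. Libraries were thinned to 66487 reads by the expected number of circRNAs that keep at least 1 or at least 2 reads. The p-values for circRNAs, loci and libraries measure the spread between these samples. They are not said to measure the spread between queens, since the labels do not say that the 3 samples of a group were separate queens. P-values for sets of circRNAs also depend on the correlation between circRNAs. The labels give no sequencing batch.

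The table pairs no circRNA with a gene. The gene table used for honey bee names is of another assembly, and coordinates were not converted between builds, so 0 circRNAs were matched to genes. The tests of summed counts per host gene and the 10 gene lists written before the data were examined were not run. In their place, and chosen after the data had been seen, circRNAs with overlapping spans on one strand were joined into 1654 loci with GenomicRanges 1.54.1, and their summed counts were tested in the same way. A locus is only a stretch of genome and need not be one gene. Of the loci, 1081 held 1 circRNA, and for these the summed count is the count of that circRNA. Overlapping circRNAs share exons and splice sites, so the split of reads between them rests on the authors' calling.

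The circRNAs named in the text follow a rule written before the data were examined. For laying vs virgin, caged vs laying and released vs caged, it takes the 10 higher and 10 lower with the largest fitted fold change among called circRNAs whose libraries do not overlap between the groups and whose mean CPM in the higher group is at least the median. Where fewer than 4 qualified in a direction, it takes the 4 with the smallest unadjusted p. It also takes the 5 most abundant circRNAs, up to 5 called in opposite directions in caged vs laying and released vs caged, and 3 per direction for the secondary comparisons. Its part for host genes, 5 per direction with the smallest p, was applied to loci.

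Alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals as the scaling, no filter, a stricter filter with a minimum count of 20, a fit of only the 2 groups compared, the replicate number as a block, limma 3.58.1 on log2 of CPM plus 1 or plus 10, and leaving out each replicate in turn. Loci as circRNAs that share a start or an end, and fits without the most abundant locus, were added after the data had been seen. Chance overlap and correlation between comparisons that share libraries were simulated 100 times with unchanged groups. Each circRNA was drawn independently, so the SD of the simulations leaves out correlation between circRNAs and may be too small.

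The fits were tested on simulated data for the 3215 circRNAs with counts under 2 set to 0, with 50 changed at each of 4 fold sizes. For laying vs virgin, 4% of 2-fold, 38% of 4-fold, 72% of 8-fold and 82% of 16-fold changes were recovered, and 1 of 3015 unchanged circRNAs was called. For caged vs laying the shares were 0%, 42%, 56% and 72%, with 3 of 3015 called. For released vs caged they were 4%, 40%, 60% and 70%, with 6 of 3015 called. The test for circRNAs of one locus that change apart (edgeR's diffSpliceDGE) was run on simulated laying vs virgin data: it found 18 of 50 loci in which 1 member changed 8-fold, 0 of 50 loci in which all members changed together, and 2 of 473 unchanged loci.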

Results

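CircRNAs were profiled in queen ovaries to ask whether they take part in ovary activation and in the control of egg laying. The 4 groups of 3 libraries were virgin queens, laying queens, queens caged for 7 days so that laying stopped, and released queens sampled on day 8, when they were laying again. The virgin libraries held 201414, 66487 and 119117 circRNA reads, and the laying libraries held 133403, 173922 and 89106. The caged libraries held 206697, 170382 and 176237 reads, and the released libraries held 106396, 163875 and 111025. The table listed 20244 circRNAs on 147 chromosomes or scaffolds, with spans from 150 to 99048 nt between the back-spliced ends. Of these, 12117 (59.9%) were listed in 1 library only, and 1450 (7.16%) were listed in all 12 and held 86.3% of all reads. The 3215 circRNAs that were tested held between 91.8% and 96.7% of the reads of a library. Across circRNAs, which are not independent replicates, log CPM correlated between libraries of one group at 0.80 to 0.87 (12 pairs). The correlation was 0.79 to 0.86 between laying, caged and released libraries (27 pairs) and 0.60 to 0.70 between a virgin library and a library of another group (27 pairs). Counts of replicates differed by more than sampling noise in each group, with a lowest chi-square per degree of freedom of 3.61, so no library was counted as a duplicate.

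The comparison of laying with virgin queens addressed ovary activation. Age, mating or cell content may also differ between these groups, so a call cannot be assigned to activation alone. In laying ovaries 401 circRNAs rose and 330 fell, which is 22.7% of those tested (edgeR quasi-likelihood test, adjusted p under 0.05). The circRNA with the highest mean in laying ovaries, ame_circ_0011734 (LG2, 4758065 to 4774296, plus strand), went from 4838 ± 3392 CPM in virgin to 38403 ± 13142 CPM in laying ovaries (SD, n = 3 each), a 9.30-fold increase (log2 fold change 3.22, SE 0.35, adjusted p = 1.70e-06). Without virgin replicate 2 its log2 fold change was 3.82. The circRNA ame_circ_0006312 (LG15, 5011343 to 5011735, plus strand) rose 5.18-fold, from 5365 ± 1484 to 24656 ± 10982 CPM (SE 0.38 on the log2 scale, adjusted p = 0.000135). The circRNA ame_circ_0000149 (scaffold GL630373.1, 79029 to 79584, minus strand) rose 2.04-fold, from 20476 ± 1570 to 37227 ± 2965 CPM (adjusted p = 0.00135). Of the 5 most abundant circRNAs, the remaining ones were not called: ame_circ_0017693 (LG7, 640672 to 648915, minus strand) was at 24376 ± 4713 CPM in virgin and 17994 ± 3661 CPM in laying ovaries, and ame_circ_0009157 (LG1, 21227866 to 21228686, minus strand) was at 19516 ± 1985 and 13514 ± 1456 CPM. The latter was called lower by DESeq2, with library totals, with the stricter filter and by limma with a pseudocount of 10 CPM.

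Of the 401 that rose, 75 were listed at 0 in all 3 virgin libraries, and of the 330 that fell, 42 were listed at 0 in all 3 laying libraries. The other 326 that rose had a median log2 fold change of 1.99, with 162 over 4-fold, and the other 288 that fell had a median of -2.02, with 148 over 4-fold. The 10 that rose with the largest fitted change were all listed at 0 in the virgin libraries. They included ame_circ_0000984 (LG10, 1313918 to 1314296, plus strand) at 413 ± 233 CPM in laying ovaries, ame_circ_0012762 (LG3, 3692605 to 3693623, minus strand) at 355 ± 10.5 CPM, ame_circ_0015433 (LG5, 5907191 to 5908645, plus strand) at 288 ± 74.8 CPM and ame_circ_0009324 (LG1, 22176287 to 22177179, minus strand) at 268 ± 43.2 CPM. The other 6 were ame_circ_0009223, ame_circ_0011794, ame_circ_0004138, ame_circ_0011207, ame_circ_0011729 and ame_circ_0011976, with laying means from 267 CPM down to 143 CPM. The adjusted p of these 10 was between 1.18e-06 and 0.00410. The 10 that fell with the largest fitted change were all listed at 0 in the laying libraries. They included ame_circ_0003849 (LG12, 852259 to 852646, minus strand) at 209 ± 146 CPM in virgin ovaries, ame_circ_0008454 (LG1, 16062339 to 16062581, plus strand) at 176 ± 43.9 CPM and ame_circ_0018189 (LG8, 13416764 to 13422383, minus strand) at 117 ± 3.07 CPM. The remaining 7, ame_circ_0001857, ame_circ_0001442, ame_circ_0014760, ame_circ_0014842, ame_circ_0004064, ame_circ_0008870 and ame_circ_0001770, had virgin means from 154 CPM down to 112 CPM. The adjusted p of the 10 that fell was between 0.000292 and 0.00958. Of these 20, ame_circ_0011976 and ame_circ_0001442 were not called by DESeq2. With library totals as the scaling, 346 circRNAs were higher and 441 lower in laying ovaries, 44.0% higher against 54.9% with TMM, and this scaling moved the median log2 fold change by -0.20. Lower calls also outnumbered higher ones by limma, at 381 against 354 with a pseudocount of 1 CPM and 513 against 426 with 10 CPM, while 216 were lower without a filter.

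**Figure D1:**
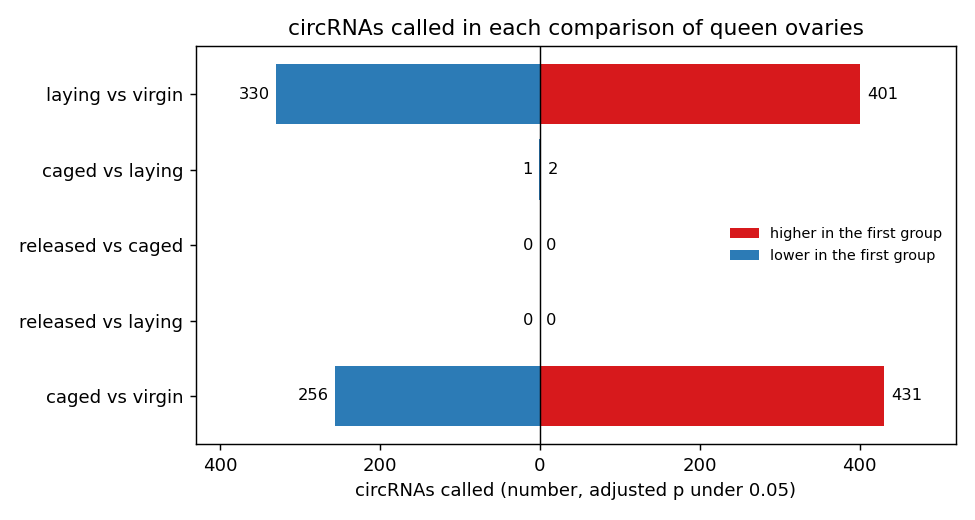
Number of circRNAs called in each comparison of queen ovaries (edgeR, adjusted p under 0.05, 3 libraries per group); bars to the right are higher and bars to the left lower in the group named first. The comparisons with virgin queens gave 731 (laying) and 687 (caged) calls, and the comparisons among laying, caged and released queens gave 3, 0 and 0; with library totals as the scaling the lower calls outnumber the higher ones in both comparisons with virgin queens.

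Summed over loci, 295 of 1654 loci rose and 253 fell in laying ovaries. The locus with the most reads, on LG2 from 4622669 to 4807227 (plus strand), rose 7.16-fold, from 14999 ± 4971 to 88898 ± 18609 CPM (log2 fold change 2.84, SE 0.22, adjusted p = 1.64e-08). Of its 31 tested circRNAs 23 rose, 0 fell and 8 were not called, and they did not change by equal amounts (edgeR's test for members that change apart, adjusted p = 1.75e-08). The uncalled ame_circ_0011722 (LG2, 4699241 to 4701723) was at 4485 ± 1435 CPM in virgin and 7319 ± 1890 CPM in laying ovaries. The locus took 1.5% ± 0.497 of circRNA reads in virgin, 8.89% ± 1.86 in laying, 7.64% ± 0.350 in caged and 8.12% ± 0.178 in released ovaries (SD, n = 3 each). The locus of 2 circRNAs on scaffold GL634653.1 from 5432 to 6423 (minus strand) rose 43.3-fold, from 65.2 ± 52.8 to 2442 ± 144 CPM (log2 fold change 5.44, adjusted p = 6.63e-09), and its log2 fold change was 6.22 without virgin replicate 3. The locus on LG9 from 10843189 to 10843764 (plus strand) rose from 78.4 ± 27.5 to 1949 ± 209 CPM (log2 fold change 4.91, SE 0.32, adjusted p = 4.02e-09). The loci on LG12 from 6735589 to 6743431 and on LG14 from 1714098 to 1733063 (both plus strand) rose 6.16-fold and 6.59-fold. Among the loci that fell, LG1 from 1120279 to 1120966 (plus strand) went from 17470 ± 1310 to 2132 ± 183 CPM, 6.89-fold lower (adjusted p = 4.12e-08). The locus of 7 circRNAs on LG7 from 1597826 to 1654071 (plus strand) went from 19900 ± 2099 to 2805 ± 583 CPM, 5.91-fold lower. The locus on LG13 from 892881 to 893128 (minus strand) was 11.4-fold lower, and those on LG12 from 9899841 to 9900083 (plus strand) and LG2 from 14879280 to 14889708 (minus strand) were 7.10-fold and 5.53-fold lower. These 10 loci kept their call in all 131 pairs of a locus and an alternative that were checked. Fits that did not hold a locus under the same bounds were not checked for it, nor were loci by shared start or end. In 105 loci 2 or more circRNAs were called, all in one direction in 91 of them and in both directions in 14. The balance of the loci called, laying vs virgin, depended on the method: lower loci outnumbered higher ones with library totals (334 against 201), DESeq2 (287 against 276), DESeq2 size factors in edgeR (275 against 269), the stricter filter (214 against 209) and only the groups compared (292 against 238).

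**Figure D2:**
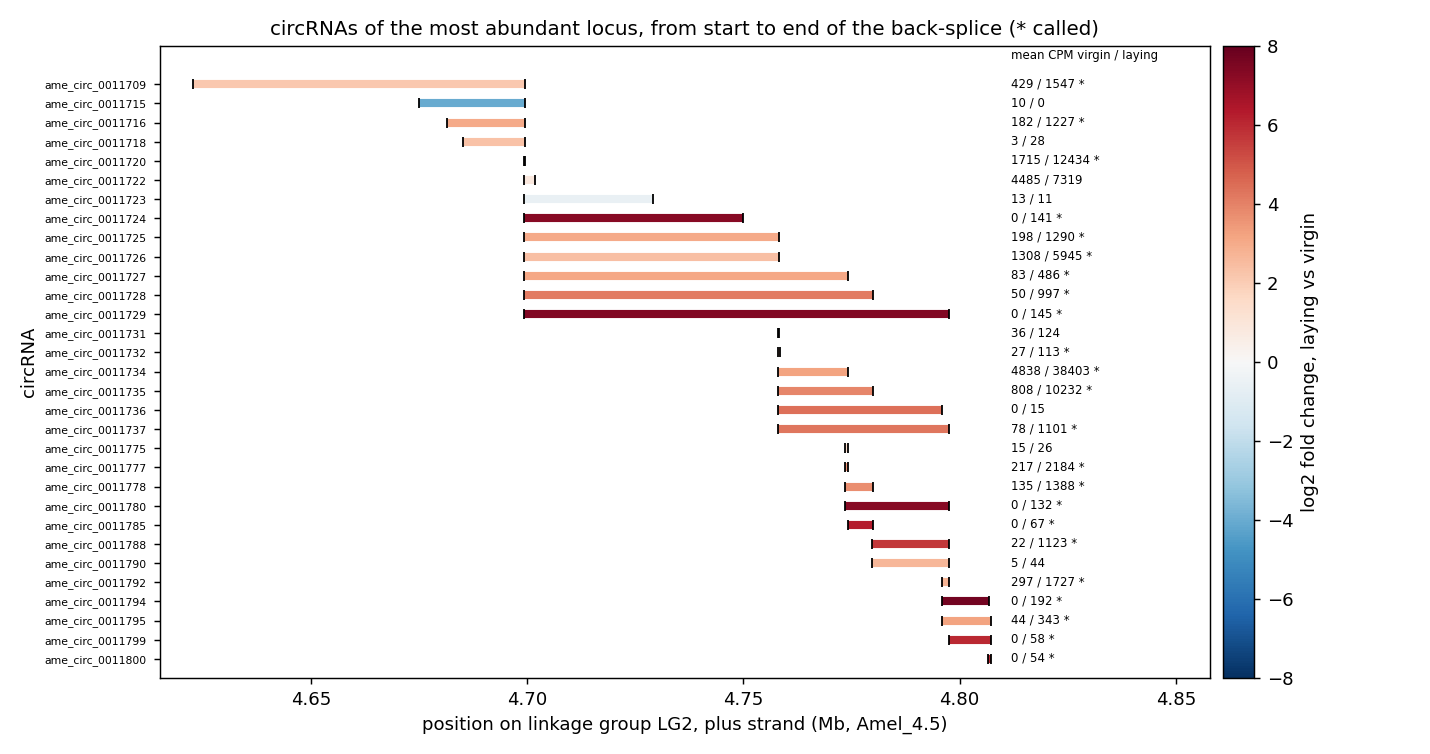
CircRNAs of the locus with the most reads, drawn from start to end of the back-splice on LG2 (Mb, Amel_4.5, plus strand); colour is the fitted log2 fold change of laying vs virgin, ticks mark the ends, and the numbers are mean CPM of 3 virgin and 3 laying libraries, with an asterisk where the adjusted p is under 0.05. Of the 31 circRNAs 23 were called higher in laying ovaries and 0 lower; fitted changes of circRNAs listed at 0 in one group depend on the prior count.

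The comparison of caged with laying queens addressed the stop of egg laying. Of 3215 circRNAs, 3 were called by edgeR, with 280 at an unadjusted p under 0.05, and DESeq2 called 27. Without a filter edgeR called 32, and with the stricter filter 1. The circRNA ame_circ_0006114 (LG15, 3022811 to 3027767, minus strand) rose 5.29-fold under caging, from 102 ± 54.8 to 532 ± 303 CPM (SE 0.46 on the log2 scale, adjusted p = 0.0466), and was at 519 ± 138 CPM in virgin and 224 ± 35.1 CPM in released ovaries. The circRNA ame_circ_0011147 (LG2, 13345342 to 13346062, plus strand) was listed at 0 in the laying libraries and at 157 ± 66.4 CPM in caged, 64.0 ± 13.1 CPM in virgin and 57.6 ± 55.1 CPM in released ovaries (adjusted p = 0.0466). The circRNA ame_circ_0015433 fell from 288 ± 74.8 to 3.91 ± 6.78 CPM (log2 fold change -5.98, SE 0.93, adjusted p = 0.0156), was at 6.10 ± 10.6 CPM in released ovaries and was listed at 0 in the virgin libraries. Its caged value is 2 reads in caged replicate 2, without which all caged libraries were at 0 and the fitted log2 fold change, which then depends on the prior count, was -8.38. The next by unadjusted p did not pass the threshold in edgeR with the low-count filter. Among these, ame_circ_0000697 (LG10, 10481070 to 10481463, plus strand) was at 484 ± 119 CPM in laying and 1273 ± 361 CPM in caged ovaries, and ame_circ_0015702 (LG5, 9141630 to 9145087, plus strand) was at 627 ± 342 and 132 ± 97.4 CPM (adjusted p = 0.108 for both). Also among them, ame_circ_0017709 was at 59.7 ± 7.76 CPM in caged ovaries and listed at 0 in laying libraries, and ame_circ_0011976 and ame_circ_0007776 were at 143 ± 36.7 and 226 ± 216 CPM in laying ovaries and listed at 0 in caged libraries. Without the filter edgeR called all 5, and DESeq2 called ame_circ_0000697 and ame_circ_0015702 (adjusted p = 0.0140 for circRNA ame_circ_0000697, caged vs laying, and the same for the latter). Also, ame_circ_0015702 and ame_circ_0007776 were called without laying replicate 3, and ame_circ_0011976 with only the groups compared. Laying replicate 3 was the lowest laying library for the first 2 of these. The laying libraries held 134, 94 and 30 reads of ame_circ_0015702 and 33, 75 and 0 reads of ame_circ_0007776. Calls that need this library left out are not counted as support. No circRNA was called without laying replicate 1, laying replicate 2 or caged replicate 3, while 1 was called without caged replicate 1 and 5 without laying replicate 3. None of the 3 calls held in all of these fits, and of the 3 only ame_circ_0006114 was also called by DESeq2, which gave no adjusted p for the others.

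**Figure D3:**
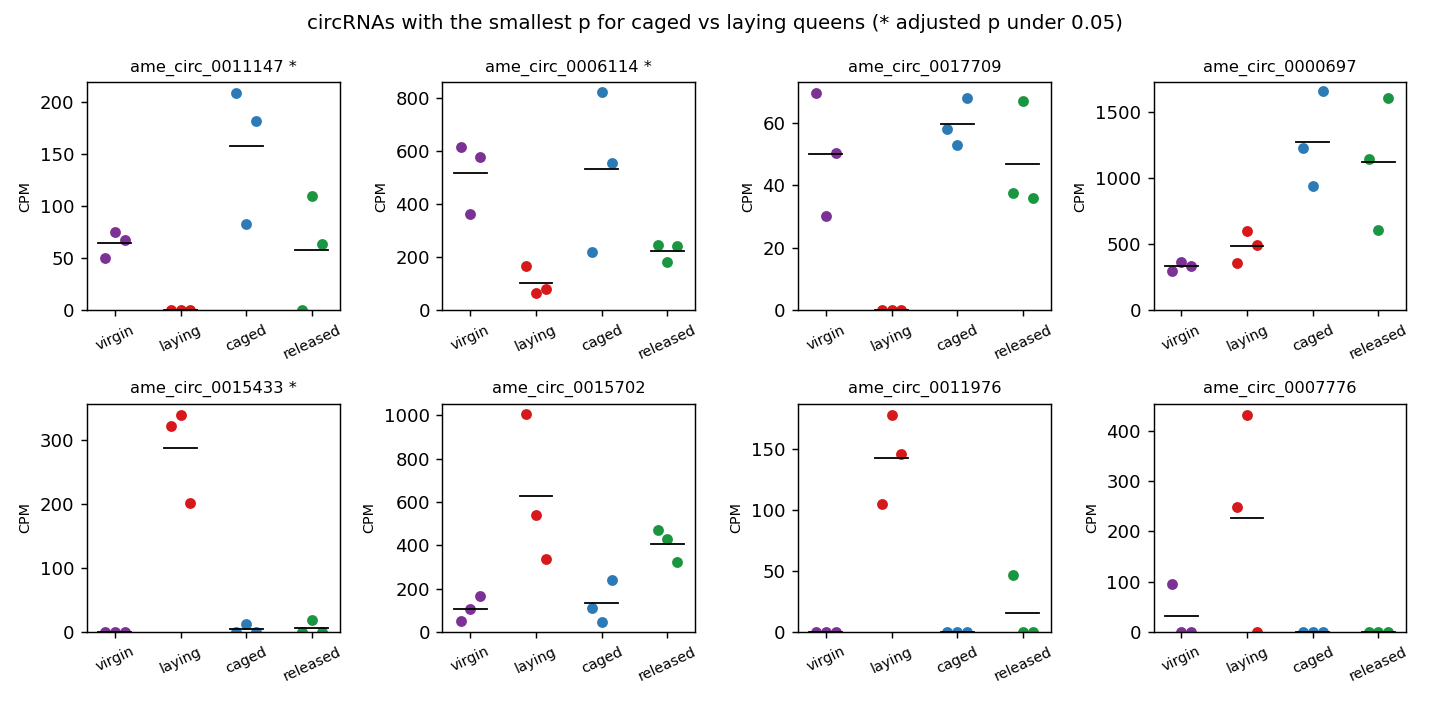
CPM of the 8 circRNAs with the smallest unadjusted p for caged vs laying queens, 4 per direction; each point is 1 library, lines are means of 3 libraries, and an asterisk marks the 3 with an adjusted p under 0.05. The caged points of ame_circ_0015433 lie near 0 (mean 3.91 CPM) where the laying mean is 288 CPM, and the released mean is 6.10 CPM.

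At the level of loci, 9 rose and 4 fell in caged ovaries, and 189 had an unadjusted p under 0.05. Some called loci held 1 circRNA, among them those of ame_circ_0011147, ame_circ_0015433, ame_circ_0017709 and ame_circ_0011976. As circRNAs, ame_circ_0017709 and ame_circ_0011976 were not called (edgeR, adjusted p = 0.108 for both). As loci both passed (edgeR, adjusted p = 0.0368), where the correction covered 1654 loci and not 3215 circRNAs. Such loci add no evidence from summing. The locus of 10 circRNAs on LG10 from 10466595 to 10490353 (plus strand) rose 2.41-fold, from 2377 ± 364 to 5514 ± 685 CPM (SE 0.26 on the log2 scale, adjusted p = 0.0368), and was at 4879 ± 2091 CPM in released ovaries. The locus on LG1 from 20346106 to 20355014 (minus strand) rose 2.36-fold, and that on LG9 from 3094010 to 3115408 (plus strand) rose 5.51-fold. The locus of 10 circRNAs on LG16 from 6919772 to 7012435 (plus strand) fell 2.71-fold, from 3810 ± 1320 to 1371 ± 609 CPM (SE 0.31, adjusted p = 0.0368), and was at 701 ± 102 CPM in virgin and 2502 ± 530 CPM in released ovaries. The locus on LG5 from 9141630 to 9164864 (plus strand) fell 3.99-fold. In 12 of the 13 called loci the change under caging had the opposite sign to that of laying vs virgin, and 11 of the 12 were also called there. Both comparisons use the laying libraries, which alone favours opposite signs, and 61.5% of all tested loci and 71.4% of the 189 with an unadjusted p under 0.05 had opposite signs. The share that unchanged groups give among called loci was not computed. No locus was called without laying replicate 1 or 2 or without caged replicate 1 or 3, and 3 were called without caged replicate 2. DESeq2 called 32 loci.

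The comparison of released with caged queens addressed the recovery of laying. No circRNA and no locus was called by edgeR or by DESeq2 with the low-count filter, although 205 circRNAs and 129 loci had an unadjusted p under 0.05, and the smallest adjusted p of a circRNA was 0.557. Without the filter edgeR called 10 circRNAs and 3 loci, and without released replicate 2 it called 2 loci. The circRNAs with the smallest unadjusted p that were higher in released ovaries included ame_circ_0003173 (LG11, 9171811 to 9186489, plus strand) at 56.4 ± 15.1 CPM in caged and 257 ± 79.6 CPM in released ovaries, and ame_circ_0012215 (LG3, 1090193 to 1091573, plus strand) at 184 ± 2.69 and 466 ± 128 CPM. In the same direction, ame_circ_0009395 and ame_circ_0005121 were listed at 0 in the caged libraries and were at 124 ± 147 and 81.6 ± 34.4 CPM in released ovaries. Lower in released ovaries were ame_circ_0003180 (LG11, 9186334 to 9188050, plus strand) at 1869 ± 1350 and 329 ± 237 CPM and ame_circ_0019202 (LG8, 8546045 to 8600528, minus strand) at 1763 ± 442 and 795 ± 343 CPM. The circRNAs ame_circ_0008049 and ame_circ_0013613 were at 92.9 ± 59.4 and 51.9 ± 26.4 CPM in caged ovaries and were listed at 0 in the released libraries. Of these 8, ame_circ_0009395, ame_circ_0005121, ame_circ_0003180 and ame_circ_0008049 were called without the filter. The 95% interval of the fold change lay within 2-fold in either direction for 439 circRNAs (13.7%) and within 4-fold for 1543 (48.0%). For caged vs laying these numbers were 406 (12.6%) and 1491 (46.4%), so for most circRNAs changes of up to 4-fold were not excluded with these libraries.

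To ask whether changes under caging went back on release, the fold changes of both steps were compared. Across circRNAs the correlation of caged vs laying with released vs caged was -0.45, where unchanged groups with shared caged libraries gave -0.43 ± 0.025 (SD of 100 simulations). The covariance was -0.648, against -0.630 ± 0.048 in the simulations. Laying vs virgin and released vs caged, which share no library, correlated at 0.064, against 0.020 ± 0.020 in simulations that ranged from -0.031 to 0.077. These simulations drew each circRNA independently, so their SD and range may understate the spread by chance.

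Released and laying queens differed in no circRNA by edgeR (232 at an unadjusted p under 0.05, smallest adjusted p 0.0641), and DESeq2 called 1. Without released replicate 2 edgeR called 2. Of the loci, LG2 from 11218336 to 11229860 (plus strand) was 4.34-fold higher in released ovaries, at 417 ± 143 against 96.6 ± 34.0 CPM (adjusted p = 0.0411), and LG5 from 5907191 to 5908645 (plus strand), the locus of ame_circ_0015433, was lower at 6.10 ± 10.6 against 288 ± 74.8 CPM (log2 fold change -5.11, adjusted p = 0.0341). Its released value is 3 reads in released replicate 2, without which all released libraries were at 0 and the fitted log2 fold change was -8.41. Without laying replicate 1, 2 or 3 or released replicate 3, 0 loci were called, and without released replicate 1, 10 were. DESeq2 called 5 loci, the stricter filter gave 0, and DESeq2 size factors in edgeR gave 1.

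Caged ovaries, although not laying, differed from virgin ovaries in 687 circRNAs, 431 higher and 256 lower, and in 500 loci. The number lower was 162 without virgin replicate 1, 166 without virgin replicate 3, 170 without caged replicate 2 and 151 without a filter. With library totals as the scaling 330 were higher and 352 lower, 48.4% higher against 62.7%, the loci went from 303 higher and 197 lower to 202 and 297, and the median log2 fold change moved by -0.23. The circRNA ame_circ_0011788 (LG2, 4779846 to 4797638, plus strand) was 44.1-fold higher in caged ovaries, at 935 ± 192 against 21.6 ± 18.9 CPM (log2 fold change 5.46, or 6.55 without virgin replicate 1). The circRNAs ame_circ_0000648 (GL634653.1, 5432 to 6423, minus strand) and ame_circ_0019528 (LG9, 10843189 to 10843584, plus strand) were 41.2-fold and 21.9-fold higher. The virgin value of ame_circ_0000648 (17.8 ± 16.9 CPM) rests on 4, 0 and 4 reads. These lie near the smallest listed count of 2, so its fold is imprecise. By limma with a pseudocount of 1 CPM the log2 fold change of circRNA ame_circ_0011788, caged vs virgin, was 6.48, and that of circRNA ame_circ_0000648, caged vs virgin, was 6.42 (5.36 by edgeR). The circRNA ame_circ_0004003 (LG12, 9899841 to 9900083, plus strand) was 12.3-fold lower, at 262 ± 46.4 against 3761 ± 779 CPM. The circRNAs ame_circ_0011407 (LG2, 14880335 to 14880582, minus strand) and ame_circ_0002658 (LG11, 14556716 to 14557296, plus strand) were 9.17-fold and 5.97-fold lower, and the adjusted p of these 6 was at most 5.53e-07. Of the circRNAs higher than in virgin ovaries, 317 were called in both laying (401) and caged (431) queens, where independent lists give 53.8. Of those lower, 180 were shared between 330 and 256, where independent lists give 26.3, and 0 were called in opposite directions. Independent lists leave out the shared virgin libraries. Simulated unchanged groups with those libraries gave a mean of 0.01 shared calls against 497 observed, but such groups leave out the effects, so this value does not measure overlap beyond shared controls. The 3 virgin libraries could not be split, so part of the excess of shared calls over independent lists may come from shared controls. The fold changes of both comparisons correlated at 0.82, against 0.52 ± 0.024 in 100 simulations of unchanged groups with shared virgin libraries, and their covariance was 3.55, against 0.749 ± 0.050.

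The number of circRNAs per library was compared after thinning. Thinned to 66487 reads, 5021 ± 909 circRNAs kept at least 1 read in virgin, 4101 ± 481 in laying, 4751 ± 47.6 in caged and 4380 ± 163 in released libraries (SD, n = 3 each). Here the virgin libraries overlapped the laying ones (exact two-sided permutation test, p = 0.3) and the caged ones (p = 0.7 by the same exact test). This threshold still depends on depth, since thinned libraries regain counts of 1 that the smallest library, virgin replicate 2, cannot hold. Virgin replicate 2 kept 4059 circRNAs at a threshold of 1 or 2 reads, and virgin replicate 1 kept 5867 and 3790. No conclusion is drawn from the threshold of 1 read. With a threshold of 2 reads, chosen after the data had been seen because no library holds a count of 1, 3905 ± 139 circRNAs were kept in virgin, 3105 ± 42.0 in laying, 3178 ± 60.5 in caged and 3300 ± 159 in released libraries (SD, n = 3 each). Without thinning, 5690 ± 1694, 4573 ± 861, 5836 ± 212 and 4812 ± 373 circRNAs were listed, and the difference between caged and virgin libraries then had the opposite sign, which turned again without virgin replicate 2. The 10 most abundant circRNAs of a library held 14.7% ± 0.341 of reads in virgin, 19.0% ± 0.628 in laying, 18.0% ± 0.560 in caged and 18.0% ± 1.25 in released libraries. The read-weighted median span was 1193 ± 104 nt in virgin, 1585 ± 51.1 nt in laying, 2075 ± 117 nt in caged and 1634 ± 230 nt in released libraries. For the number with at least 2 reads, the top-10 share and the span, every virgin library lay outside the range of the laying libraries (exact two-sided permutation test, p = 0.1 each, the smallest it allows, adjusted p = 0.233 over 35 such tests), so none could pass 0.05. In circRNAs called higher in laying than in virgin ovaries the median span was 2440 nt, and in those called lower it was 976.5 nt.

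**Figure D4:**
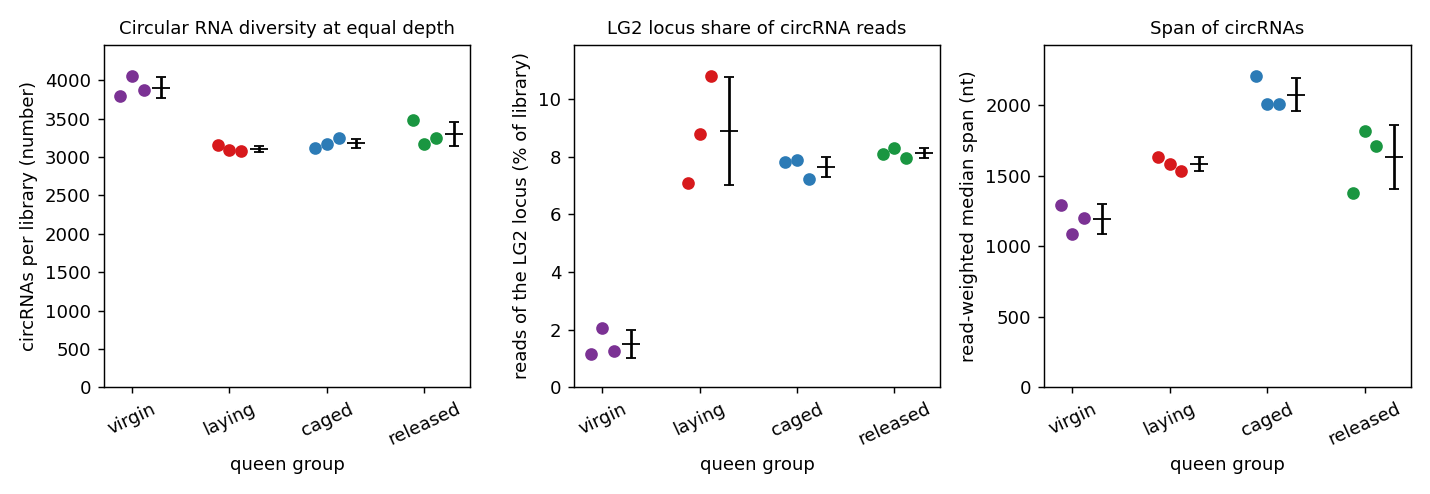
Values per library, with the mean and SD of 3 libraries in black: circRNAs with at least 2 reads after thinning to 66487 reads, reads of the LG2 locus in % of circRNA reads, and the read-weighted median span in nt. Virgin libraries averaged 3905 circRNAs, 1.5% and 1193 nt, against 3105 circRNAs, 8.89% and 1585 nt in laying libraries.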

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

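The loci, their alternative definition, the fits without the most abundant locus and thinning to at least 2 reads were chosen only after the data had been seen, and the other alternatives were planned. The number of circRNAs called stayed within 1.5 times for laying vs virgin (573 to 939 across alternatives, 521 to 666 when 1 replicate was left out) and for caged vs virgin (519 to 795, and 472 to 579). The numbers by direction moved more: the 256 lower in caged vs virgin were 151 with no filter, 162 without virgin replicate 1, 166 without virgin replicate 3 and 170 without caged replicate 2, and the 330 lower in laying vs virgin were 216 with no filter and 513 by limma with 10 CPM. The total numbers of loci stayed within 1.5 times, at 400 to 563 and 387 to 480 for laying vs virgin, and at 351 to 509 and 378 to 437 for caged vs virgin. The replicate numbers did not pair the samples, since residual correlations were -0.16 to 0.11 in 18 pairs with one number and -0.10 to 0.12 in 36 other pairs; with the replicate block 673 circRNAs were called for laying vs virgin and 596 for caged vs virgin.

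The small counts moved, and the cause was not tested unless stated. For caged vs laying (3 circRNAs), DESeq2 called 27, no filter gave 32, the stricter filter 1, the replicate block 1, and limma 0 with a pseudocount of 1 CPM and 1 with 10 CPM; leaving out 1 replicate gave 0 to 5. For its 13 loci these were 32 with DESeq2, 31 with no filter, 2 with the stricter filter, 5 with only the groups compared, 5 with the replicate block, and 0 to 9 without 1 replicate. For released vs caged (0), no filter gave 10 circRNAs and 3 loci, and leaving out 1 replicate gave 0 to 0 circRNAs and 0 to 2 loci. For released vs laying (0 circRNAs), DESeq2, only the groups compared, the replicate block and limma with 10 CPM each called 1, no filter gave 11, and leaving out 1 replicate gave 0 to 2. For its 2 loci, DESeq2 called 5, DESeq2 size factors in edgeR 1, no filter 14, the stricter filter 0, only the groups compared 1, loci by shared start or end 1, and leaving out 1 replicate gave 0 to 10.

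The difference in circRNAs listed per library between released and caged queens (-1024) was -502 at 5 reads or more, -371.5 after thinning to at least 1 read and 122 after thinning to at least 2. Values after thinning to at least 1 read still depend on depth, since deeper libraries regain counts of 1 when thinned. Between caged and laying queens (1263) it was 530 at 5 reads or more, 650 and 72.9 after thinning to at least 1 and 2 reads, and 792 without laying replicate 3. For circRNAs detected per library, laying vs virgin (-1117), it was -333 at 5 reads or more, -242.5 without virgin replicate 1, -1933 without virgin replicate 2 and -646 without laying replicate 3. Between caged and virgin queens (146) it was 197 at 5 reads or more, -270 after thinning to at least 1 read, -728 to at least 2, and -670 to 1021 when 1 replicate was left out, with the negative value without virgin replicate 2, the smallest library. For circRNAs detected per library, released vs laying (239), it was 28 at 5 reads or more, 39 without released replicate 2, -232 without laying replicate 3 and at most 612. The correlation of caged vs laying with released vs caged (-0.45) was -0.51 with the stricter filter and -0.56 to -0.36 without 1 replicate. No named circRNA or locus reversed in the fits in which it was checked. Counted over pairs of a named item and an alternative, calls were lost in 2 pairs for laying vs virgin circRNAs, 24 for caged vs laying circRNAs, 57 for caged vs laying loci and 12 for released vs laying loci, and gained in 4, 10 and 4 pairs for laying vs virgin, caged vs laying and released vs caged circRNAs. DESeq2 gave no adjusted p for some named circRNAs, which are left out. Fits that did not hold a named circRNA, or a named locus under the same bounds, are left out too. The host gene tests and host gene lists (10) were not run. Whether the low counts for caged vs laying (3) and released vs caged (0) reflect few real changes or a lack of power was not separated: the 95% interval lay within 2-fold for 12.6% and 13.7% of circRNAs, and 42% and 40% of simulated 4-fold changes were recovered.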

Other observations

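Chosen only after the result was seen were the test of members that change apart as a whole, the sets from comparisons without shared libraries, the scaling and back-splice tests of the LG2 locus, and both tests of spans without the most abundant circRNAs. CircRNAs of one locus did not always change together. In laying vs virgin ovaries, members changed apart in 78 of the 573 loci with 2 or more circRNAs (13.6%; edgeR, adjusted p under 0.05). In the locus on LG1 from 18150632 to 18167182 (minus strand, 7 circRNAs, adjusted p = 3.40e-10), ame_circ_0008724 (18161283 to 18167182) rose from 156 ± 47.2 to 906 ± 18.5 CPM (SD, n = 3 each, edgeR). In the same locus ame_circ_0008722 (18160207 to 18167182), which shares its end, fell from 406 ± 77.1 to 73.3 ± 28.6 CPM. In the locus on LG16 from 4458980 to 4468298 (minus strand, adjusted p = 3.79e-07), ame_circ_0007233 (4458980 to 4459495) fell from 855 ± 89.8 to 226 ± 49.2 CPM, while ame_circ_0007234 (4458980 to 4465010), with the same start, rose from 852 ± 98.9 to 2372 ± 296 CPM. These 4 circRNAs were chosen after their values were seen. For caged vs virgin 71 loci passed, for caged vs laying 1, for released vs caged 1, and for released vs laying 0 (33 at an unadjusted p under 0.05; edgeR, no other tool was run).

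Members that change apart may reflect a switch of back-splice sites within a locus, a hypothesis from these data. The test finds unequal changes, which need not be opposite. Among all loci, 14 held a circRNA called higher and one called lower, and how many of these are among the 78 was not counted. Among the 1448 circRNAs that were listed in all 12 libraries and tested, 67 of 256 loci passed (26.2%). This share argues against low counts and missing single reads. After each library's trend with span was removed, 75 of the 78 loci (96.2%) passed, which argues against a trend with genomic span as the whole cause. Span is the distance between the ends on the genome and need not be the length of the RNA. A bias by the length of the RNA was not tested. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. Only 1 split, the real one with 78 loci, gave as many, and the highest other gave 2. Other splits mix the groups, so a real difference enters their spread, and no conclusion is drawn from them. Overlapping genes, the authors' calling and the queens' age or mating stay open as untested.

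The LG2 locus was itself among the 78 loci whose members changed apart (adjusted p = 1.75e-08 in edgeR), and among called members listed in both groups the log2 fold change ran from 2.17 (ame_circ_0011709) to 5.69 (ame_circ_0011788), so its rise was not one common change. With scaling taken from the other circRNAs only, the log2 fold change of its summed counts was 2.84 with TMM. It was 2.71 with size factors and 2.65 with library totals. The locus held at most 10.8% of the reads of a library, so leaving it out could change the totals only slightly. The test could therefore not have shown a scaling set by the locus itself, and no conclusion is drawn from it. Of 22 members that share neither end with the most abundant one, 17 were called higher. This argues against reads of the back-splice of the most abundant circRNA alone being listed as many circRNAs. Members also share other ends, and 9 of the 31 tested members start at 4699241. Whether reads of another shared site were split over many circRNAs was not tested. After the span trend was removed the log2 fold change of the sum was 2.76. Over all tested circRNAs the median log2 fold change was -0.63 for spans up to 300 nt and 0.20 over 10000 nt. Removing a trend of this size could not take away the rise of the locus, so no conclusion on span bias is drawn. Differences in age, mating or cell content between virgin and laying queens stay open as untested.

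Read-weighted spans were shorter in virgin than in laying libraries by a mean of 392 nt. Without the 100 most abundant circRNAs the difference was 342 nt and the groups did not overlap, which argues against a few abundant circRNAs as the whole cause. Caged libraries exceeded laying ones by 491 nt, and without the 100 most abundant circRNAs by 154 nt with overlap, which is what a few abundant circRNAs would give. With each library's span trend removed, 684 of the 731 circRNAs called for laying vs virgin (93.6%) were still called. For caged vs virgin 574 of the 687 were still called, and all calls were then 364 higher and 297 lower, against 431 and 256. For caged vs laying 1 of the 3 was still called, released vs laying had 1 call and released vs caged had 0. Differences in RNA integrity or RNase R digestion may still shift spans, and no value for either was used here.

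For the other counts, too, 10 splits are too few for a share under 0.05. Every other split also puts libraries of both groups on each side. A real difference then enters the spread and lowers the number of calls, so no conclusion is drawn from these counts. For laying vs virgin 731 circRNAs and 548 loci stood against a highest other split of 0 and 0 (1 split each as large, the real one). For caged vs virgin 687 and 500 stood against 1 and 1 (1 split each). For caged vs laying 3 circRNAs and 13 loci stood against 0 and 0 (1 split each). For released vs caged 0 and 0 stood against 2 and 0 (10 splits each as large; DESeq2 also called 0 and 0, and 205 circRNAs and 129 loci had an unadjusted p under 0.05 in edgeR). For released vs laying 0 circRNAs (10 splits as large; 232 at an unadjusted p under 0.05 in edgeR, 1 call by DESeq2) stood against 1, and 2 loci against 0 (1 split).

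Sets of circRNAs called against virgin queens were tested between groups outside the comparison that gave them. Of 6 such tests by limma's camera, which compares a set with the other circRNAs, 1 passed. The 431 circRNAs higher in caged than in virgin ovaries had a median log2 fold change of -0.11 in released vs laying queens. By camera their adjusted p was 0.00550, and 0.360 with an estimated correlation. By limma's fry the unadjusted p of this set was 0.0856.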
